A study of Homo sapiens with 6 samples.

How the data were processed

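Total RNA of 6 HEK293 samples, 3 wild type and 3 with stable SFXN2 overexpression, was depleted of ribosomal RNA and made into libraries with the TruSeq RNA v2 kit, per the labels' protocols. This kit does not mark the strand, so reads of a gene and of its antisense partner cannot be told apart. Protein-coding genes held 94.5 ± 0.81% of counts in wild type and 94.5 ± 0.28% with overexpression (SD, n = 3 each). Nuclear small structural RNAs held 0.0065 ± 0.0010% and 0.0068 ± 0.0014% (SD, n = 3 each). The counts therefore do not by themselves bear out a preparation from total RNA, which is taken from the labels. Reads were trimmed with Trim Galore 0.4.4 and the genome build was hg38, per the submitters' processing notes. The aligner, the counting tool and the annotation release are not given in the sources used here.

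The authors deposited a table of raw counts for 60564 Ensembl genes in the 6 samples, per the file headers and the values, which are whole numbers with a different total in each sample. Of these genes 26580 had no count in any sample. The authors also deposited a log2 table of 35778 genes, whose values equal the log2 of the count divided by a constant per sample, plus 1. Column names gave the group and replicate. The sample titles name the groups NC_HA and OE_HA, and the genotype label and the series' design text give NC_HA as wild type. What NC and HA stand for is not given in the sources used here, and the labels name no vector or tag control. Gene positions and types came from GENCODE 29 on GRCh38, matched by Ensembl ID for 58457 genes holding 99.95% of counts. All list members were found by current or older symbol.

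Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with a minimum count of 10, which left 18797 genes, and the robust quasi-likelihood F-test with group as the term, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values per group are TMM-scaled CPM, given as mean ± SD. The SE of a log2 fold change was its size over the square root of the F statistic, and 95% intervals used the test's total degrees of freedom. Counting floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. The median SE was 0.17 on the log2 scale and the common biological coefficient of variation 0.20.

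Before the data were examined, 35 pathway lists and 6 lists of markers of other cell types were fixed, together with the tests, the other settings to try and the rule for named genes. Lists were tested two-sided with limma 3.58.1 camera (preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the pathway lists and over the marker lists separately, and again with an estimated correlation and with fry. A list's median leaves out SFXN2. Median and camera direction differed in sign for several lists, among them pro-apoptotic genes, ATF4 targets, the mitochondrial unfolded protein response, NRF2 targets, cholesterol synthesis and fibroblast markers, none of which passed. The mean alone had the opposite sign for the lists of iron handling, immediate-early genes, TGF-beta targets and epithelial markers. Named genes were SFXN1 to SFXN5, PINK1 and further fixed genes which, with 1 pathway list, are not reported here; the 10 genes with the largest increase and the 10 with the largest decrease past the threshold at 2 CPM or more with separate groups, which gave SFXN2 alone; in each list up to 4 members past the threshold, or the 2 with the smallest p; and the 5 most abundant genes, with XIST and Y-linked genes left out of tables and plots. C1QTNF3-AMACR, C1QTNF3, AMACR, GPR50, CGA, BAX, MCL1, CDKN1A, PHGDH, TNFAIP3, HIST1H4H, MT-RNR1 and the genes named only in the closing part were chosen after their values were seen.

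Samples with the same replicate number deviated together from their group means. The correlations over genes were 0.24, 0.33 and 0.19 for numbers 1, 2 and 3, each above 0.1. All correlations between different numbers were negative, which is not separate support. Deviations from a group mean cancel within each group, so positive same-number values push the others below zero. With 3 samples per group few matchings exist, so the numbered one can also be the best by chance. The numbers were therefore taken as pairing the samples, from the data and not from a stated design, and a fit with the replicate number as a block stands beside the results whose call it changes. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom 13.7 or more for every pair of libraries), so all were kept as separate samples.

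Other settings fixed at that stage were median-of-ratios scaling, library size alone, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 1 CPM in 3 samples, the replicate block, removal of structural RNAs and mitochondrial-genome genes, limma on the deposited log2 table, stricter thresholds, and leaving out each sample. Cyclic loess scaling, a correction for GC content and that correction with the block were added after seeing the data. The steps were tested on simulated counts of 18361 genes with 200 changed genes. For this comparison edgeR recovered 23.9% of 67 genes changed 1.5-fold, 80.6% of 67 changed 2-fold and 97.0% of 66 changed 4-fold, with 13 unchanged genes called. DESeq2 recovered 37.3%, 86.6% and 97.0%, with 44 unchanged genes called. The changed genes were drawn from those at 1 CPM or more. With 200 genes changed at once, the adjusted threshold is easier to pass than in these data, where 2 genes passed. The rates therefore do not give the chance of finding a single changed gene here. A simulated 1.3-fold rise of the complex I list was recovered, with 0 other lists called. The simulated genes varied independently of each other, whereas the estimated correlation within the complex I list was 0.45 in the data. The simulation therefore does not measure how often lists are called falsely here.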

Results

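RNA sequencing was run on HEK293 cells, an established human embryonic kidney cell line, in 2 states. The wild-type group had 3 samples and the group with stable overexpression of SFXN2 had 3 samples. SFXN2 encodes sideroflexin 2, a carrier protein of the mitochondrial membrane. The series title links SFXN2 to apoptosis after mitochondrial dysfunction. The comparison of overexpression with wild type therefore asks which transcripts differ when SFXN2 is raised. Total gene counts were 32121527, 41217867 and 35839222 in wild-type replicates 1, 2 and 3, and 40043248, 52958006 and 59963713 in overexpression replicates 1, 2 and 3. The group means were about 36392900 ± 4573370 (SD, n = 3) and 50988300 ± 10105200 (SD, n = 3). The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

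SFXN2 rose about 48-fold with overexpression, and no other gene with a mean above 2 CPM passed in edgeR (CPM, a gene's count scaled to a common library total). DESeq2 called further genes, given below. The gene (ENSG00000156398) lies on chromosome 10 from 102714538 to 102743492 in GRCh38. Its level was 36.3 ± 8.44 CPM (SD, n = 3) in wild type and 1734 ± 196 CPM (SD, n = 3) in the overexpression group. The raw counts were 1155, 1144 and 1580 in the wild-type replicates and 59139, 104997 and 108224 in the overexpression replicates, so each library matched its label. The log2 fold change was 5.58 (SE 0.20, 95% interval 5.13 to 6.02, adjusted p = 2.3e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Counts of the cell's own transcript and of the construct were not separated. The construct may lack untranslated ends, so its counts may understate it. The related carriers stood at similar levels in both groups. SFXN1, a mitochondrial serine transporter, stood at 170 ± 19.3 CPM (SD, n = 3) in wild type and 167 ± 16.9 CPM (SD, n = 3) with overexpression. The log2 fold changes of SFXN3, SFXN4 and SFXN5 were -0.27, 0.0075 and -0.0049, all with adjusted p of 0.93 or more in edgeR. The list of sideroflexins without SFXN2 itself had a median log2 fold change of -0.013 (camera adjusted p = 0.835).

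**Figure D1:**
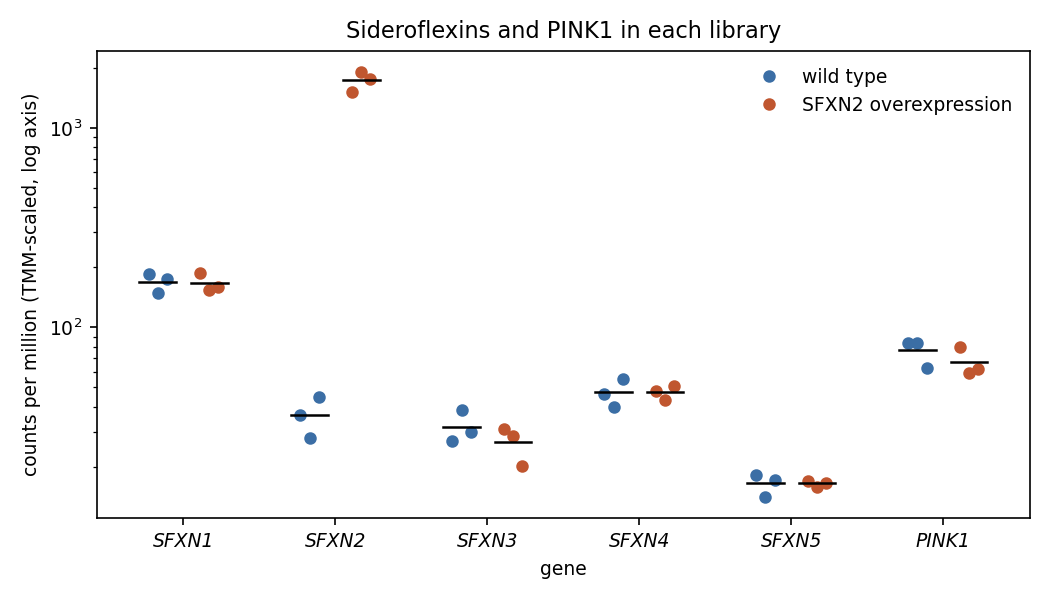
CPM (log axis) of the 5 sideroflexin genes and PINK1 in each of the 3 wild-type (blue) and 3 SFXN2 overexpression (orange) libraries; each point is a library and each black line a group mean. SFXN2 lies at 36.3 CPM on average in wild type and at 1734 CPM with overexpression, while the points of both groups lie close together or overlap for the other genes.

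In all, 2 of 18797 tested genes passed an adjusted p of 0.05 in edgeR, both of them higher with overexpression. The second was C1QTNF3-AMACR (ENSG00000273294; chromosome 5, 33987174 to 34124528), a read-through gene model that joins the neighbouring genes C1QTNF3 and AMACR. It is named here after its values were seen. It had no count in any wild-type library and 80, 136 and 78 counts in overexpression replicates 1, 2 and 3, which is at least 70.0-fold higher against a floor of 3 counts over the wild-type group (adjusted p = 0.0386 by edgeR). With the replicate number as a block its adjusted p was 0.0744, so that 1 gene was left, and leaving out each library in turn gave 0.028 to 0.167, with the call kept only without overexpression replicate 3. Its level, 1.94 ± 0.61 CPM (SD, n = 3), was low, and reads of overlapping gene models cannot be assigned with certainty. AMACR, a racemase of branched-chain fatty acid breakdown, stood at 18.1 ± 2.60 CPM (SD, n = 3) in wild type and 16.95 ± 0.43 CPM (SD, n = 3) with overexpression. C1QTNF3, which encodes a secreted protein of the C1q family, stood at 1.91 ± 0.61 CPM (SD, n = 3) and 1.13 ± 0.29 CPM (SD, n = 3).

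No gene was lower at the threshold in edgeR (0 genes), although 448 had a lower level at an unadjusted p below 0.05. The unadjusted p was below 0.05 for 895 genes in all, where 940 would be found by chance if no gene differed. With the replicate number as a block it was below 0.05 for 1563 genes, more than that chance number, with 1 gene past the adjusted threshold, and with GC correction and the block for 1407 genes, with 4 past it. Leaving out a library gave 1505 genes (wild-type replicate 1), 943 (wild-type replicate 2), 560 (wild-type replicate 3), 2295 (overexpression replicate 1), 363 (overexpression replicate 2) and 304 (overexpression replicate 3), so the count depends on which libraries are kept. DESeq2 called 9 genes, 6 higher and 3 lower, and limma-voom called 3, all higher. The DESeq2 calls outside edgeR's included GPR50, an orphan receptor of the melatonin receptor family, at 87.1 ± 14.6 CPM (SD, n = 3) in wild type and 48.9 ± 6.25 CPM (SD, n = 3) with overexpression (DESeq2 adjusted p = 0.00061, edgeR adjusted p = 0.844). They also included CGA, the shared alpha subunit of the glycoprotein hormones, at 0.81 ± 0.29 and 2.54 ± 0.21 CPM (SD, n = 3 each; DESeq2 adjusted p = 0.03, edgeR adjusted p = 0.93). With the replicate number as a block the edgeR adjusted p was 0.0744 for GPR50 and 0.461 for CGA, neither past the threshold. The 95% interval of the log2 fold change lay within -1 to 1 for 13643 genes (72.6%), so for the remaining genes these libraries leave a log2 change of 1 open.

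**Figure D2:**
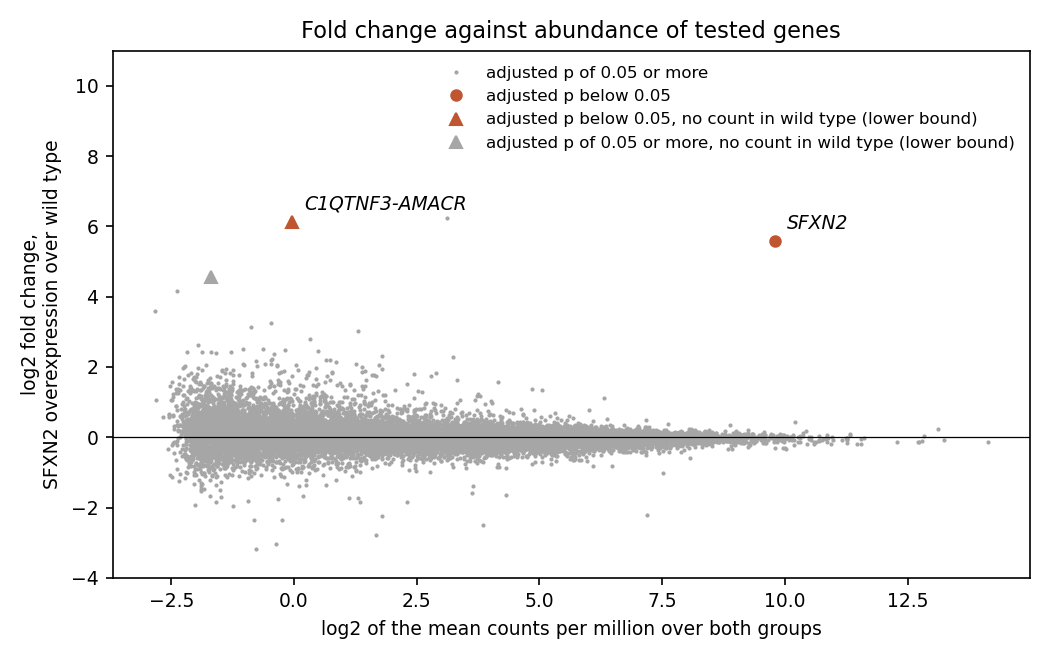
Log2 fold change of SFXN2 overexpression over wild type (vertical axis) against the log2 of the mean CPM over both groups (horizontal axis); each point is a tested gene, and triangles mark the lower bound for genes without a count in wild type. SFXN2 at 5.58 and C1QTNF3-AMACR, at least 70.0-fold higher, are the genes with an adjusted p below 0.05 in edgeR.

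Transcripts of mitophagy and cell death genes did not differ at the threshold, and RNA levels do not measure these processes themselves. PINK1, a kinase that accumulates on damaged mitochondria, stood at 76.7 ± 11.9 CPM (SD, n = 3) in wild type and 67.0 ± 11.4 CPM (SD, n = 3) with overexpression, with a 95% interval of the log2 fold change from -0.53 to 0.14. In the list of mitophagy and mitochondrial dynamics, 0 of 38 tested members passed in edgeR, and 37 had a 95% interval within -1 to 1. Its smallest unadjusted p values belonged to USP15, a deubiquitinase (log2 fold change 0.26), and RHOT2, a GTPase of the mitochondrial outer membrane (-0.28). Of 31 pro-apoptotic genes none passed, and their median log2 fold change was -0.0034 (camera adjusted p = 0.931). Their smallest unadjusted p values belonged to TRADD (log2 fold change -0.61) and FAS (0.25), both with an edgeR adjusted p of 0.93. TRADD, the largest change in the list, stood at 4.20 ± 0.64 and 2.76 ± 0.39 CPM (SD, n = 3 each). BAX, an effector of mitochondrial outer membrane permeabilization, stood at 58.1 ± 1.73 and 51.3 ± 3.46 CPM (SD, n = 3 each). The 19 tested anti-apoptotic genes had a median of 0.061 (camera adjusted p = 0.639), with MCL1 at 193 ± 19.0 and 201 ± 33.2 CPM (SD, n = 3 each). CDKN1A, a cyclin-dependent kinase inhibitor, had a log2 fold change of 0.069.

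Transcripts of the respiratory chain were likewise close in both groups. The mitochondrial genome took 7.22 ± 0.99% of counts (SD, n = 3) in wild type and 7.14 ± 0.46% (SD, n = 3) with overexpression. The median log2 fold change of its 13 mRNAs was -0.091 (camera adjusted p = 0.468), and MT-CO3, a core subunit of cytochrome c oxidase, had a log2 fold change of -0.13. The 38 nuclear genes of complex I had a median of 0.045 (camera adjusted p = 0.707), and the 38 nuclear genes of complexes II to V a median of 0.017 (camera adjusted p = 0.931). All members of both nuclear lists had 95% intervals within -1 to 1. Their smallest unadjusted p values belonged to COX7B, at 67.7 ± 4.55 and 84.9 ± 6.05 CPM (SD, n = 3 each), and CYC1, at 107 ± 13.5 and 87.5 ± 9.66 CPM (SD, n = 3 each), both with an edgeR adjusted p of 0.93. The 42 genes of the mitochondrial ribosome and translation had a median of 0.018 (camera adjusted p = 0.835). Complex I passed as higher without overexpression replicate 2 (0.0298), complexes II to V as lower without overexpression replicate 1 (0.0495) and the mitochondrial ribosome as lower without wild-type replicate 2 (0.0042).

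The lists of metabolism and hypoxia gave small values, among them serine, heme and iron metabolism, which are tied to sideroflexins. The 30 genes of serine and one-carbon metabolism had a median log2 fold change of -0.094 (camera adjusted p = 0.312). PHGDH, which starts serine synthesis, stood at 555 CPM in wild-type replicate 2 and between 194 and 223 CPM in the other 5 libraries. The 31 genes of heme synthesis and iron-sulfur clusters had a median of 0.012 (camera adjusted p = 0.944), and ALAS1, which starts heme synthesis, stood at 35.0 ± 5.79 and 44.8 ± 5.07 CPM (SD, n = 3 each; edgeR adjusted p = 0.93). The 21 tested genes of iron handling and ferroptosis had a median of -0.027 (camera adjusted p = 0.853), with the iron transporter SLC11A2 at 68.5 ± 0.96 and 55.8 ± 5.88 CPM (SD, n = 3 each; edgeR adjusted p = 0.93). The medians were -0.057 for the tricarboxylic acid cycle (23 genes, camera adjusted p = 0.324), -0.11 for glycolysis (25 genes, 0.153), -0.10 for fatty acid synthesis (17 genes, 0.153) and 0.012 for cholesterol synthesis and uptake (26 genes, 0.847). For 28 tested hypoxia-inducible genes the median was -0.12 (camera adjusted p = 0.312). The tricarboxylic acid cycle, glycolysis, fatty acid synthesis and cholesterol lists passed as lower without wild-type replicate 2 (adjusted p = 0.0061, 0.0033, 0.0034 and 0.0034) and without overexpression replicate 1 (0.0495, 0.019, 0.0040 and 0.045). Hypoxia-inducible genes passed as lower without wild-type replicate 1 (0.034) or overexpression replicate 1 (0.014), and glycolysis also with DESeq2 (0.037).

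Stress responses that follow mitochondrial damage did not pass either. The 38 genes of ATF4 and the integrated stress response had a median of -0.021 (camera adjusted p = 0.871). DDIT3, which encodes the stress transcription factor CHOP, stood at 11.1 ± 3.35 and 21.7 ± 11.8 CPM (SD, n = 3 each; edgeR adjusted p = 0.93). The mitochondrial unfolded protein response (21 genes) had a median of 0.012, the endoplasmic reticulum unfolded protein response (25 genes) 0.029, oxidative stress and NRF2 targets (29 genes) -0.025 and the heat shock response (23 genes) 0.0078, with camera adjusted p of 0.931, 0.805, 0.931 and 0.805. The lists of autophagy and lysosome (40 genes), the ubiquitin-proteasome system (40 genes), cytosolic ribosomal proteins (53 genes) and calcium signalling at mitochondria and endoplasmic reticulum (24 genes) had medians of -0.012, 0.020, -0.0062 and -0.017 and camera adjusted p of 0.835, 0.835, 0.847 and 0.468. HSPA5, the main endoplasmic reticulum chaperone, stood at 417 ± 77.2 and 533 ± 84.5 CPM (SD, n = 3 each; edgeR adjusted p = 0.93). Without wild-type replicate 2 the ATF4 list passed as higher (0.00019) and the heat shock and ubiquitin-proteasome lists as lower (0.0026 and 0.0015). Without overexpression replicate 1 the ATF4 list passed as higher (0.045) and cytosolic ribosomal proteins as lower (0.0495).

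Of 35 pathway lists, 4 passed camera with its preset correlation, and none of the 4 calls held when camera estimated the correlation between genes, in the fit with or without the replicate block. The 20 tested genes of NF-kB signalling and inflammatory cytokines rose as a list, with a median log2 fold change of 0.53 (adjusted p = 0.0033; adjusted p = 0.97 with an estimated correlation) and 18 members with a positive value. RELB, a subunit of NF-kB, stood at 1.47 ± 0.32 and 4.90 ± 3.33 CPM (SD, n = 3 each), and TNFAIP3, an NF-kB target that restrains the pathway, at 10.6 ± 1.58 and 21.6 ± 11.3 CPM (SD, n = 3 each). The 14 tested replication-dependent histone genes rose as a list (median 0.57, adjusted p = 0.016; adjusted p = 0.97 with an estimated correlation), with a median level of 0.48 CPM and HIST1H4H at 3.31 ± 0.40 and 8.24 ± 7.56 CPM (SD, n = 3 each). The 18 tested Wnt pathway targets fell as a list (median -0.15, adjusted p = 0.022; adjusted p = 0.97 with an estimated correlation), with the Wnt receptor FZD7 at 28.2 ± 1.199 and 24.1 ± 1.01 CPM (SD, n = 3 each). The 24 tested genes of fatty acid oxidation also fell as a list (median -0.086, adjusted p = 0.040; adjusted p = 0.97 with an estimated correlation), with CPT1A, which admits long-chain fatty acids to mitochondria, at 23.4 ± 6.49 and 18.0 ± 2.63 CPM (SD, n = 3 each). Among 10000 random lists matched on expression, the fatty acid oxidation median lay at percentile 2.55, within the middle 95% of the random medians, and the Wnt median at 0.32. The self-contained test fry gave 0 lists. With an estimated correlation camera gave an adjusted p of 0.97 for every pathway list, so that value is not particular to these 4. Its unadjusted p was 0.199 for NF-kB, 0.285 for histones, 0.118 for Wnt targets and 0.233 for fatty acid oxidation. The simulated complex I rise was not put through this version, so its power here is unknown. No member of these lists passed alone in edgeR. Histone genes took only 0.0111 ± 0.0012% of counts in wild type and 0.0181 ± 0.0090% with overexpression (SD, n = 3 each). A further 16 members of the histone list were not tested, so its call rests mostly on weakly counted genes.

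The NF-kB and histone lists were highest in overexpression replicates 2 and 3. Relative to the wild-type mean, the mean log2 CPM of the NF-kB list was -0.084 in overexpression replicate 1, 1.16 in replicate 2 and 0.75 in replicate 3, against -0.25, 0.37 and -0.12 in wild-type replicates 1, 2 and 3, so that it was higher with overexpression in all 3 numbered pairs. For the histone list it was -0.11, 0.63 and 1.18, against 0.11, 0.081 and -0.19, higher with overexpression in the pairs numbered 2 and 3 and lower in pair 1. The pairs were themselves inferred from these data, so agreement between them is weak support. TNFAIP3 stood at 8.60, 26.7 and 29.4 CPM in overexpression replicates 1, 2 and 3, against 9.81, 12.4 and 9.53 CPM in wild type. It was thus lower with overexpression in pair 1, as was RELB (1.13 against 1.52 CPM), and both were higher in pairs 2 and 3. Overexpression replicates 2 and 3 were also the deepest libraries and the ones with most genes counted (28985 and 29154, against 24466 to 26127 in the other 4). Markers of neurons and of blood and immune cells lay higher in the same libraries, at 0.59 and 0.81 and at 1.25 and 1.303, without passing as lists. The NF-kB call was lost without overexpression replicate 2 (adjusted p = 0.125) and with a filter of 1 CPM (0.101). The histone call was lost without overexpression replicate 3 (0.184) and without wild-type replicate 3 (0.141). The Wnt call was lost without wild-type replicate 3 (0.118), overexpression replicate 2 (0.066) or overexpression replicate 3 (0.264). The fatty acid oxidation call was lost without wild-type replicate 1 (0.073) or 2 (0.173), without overexpression replicate 2 (0.137) or 3 (0.282), and with a filter of 1 CPM (0.082). Cyclic loess scaling ended the histone, Wnt and fatty acid oxidation calls (0.096, 0.068 and 0.096), while their medians moved little, to 0.54, -0.13 and -0.076.

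**Figure D3:**
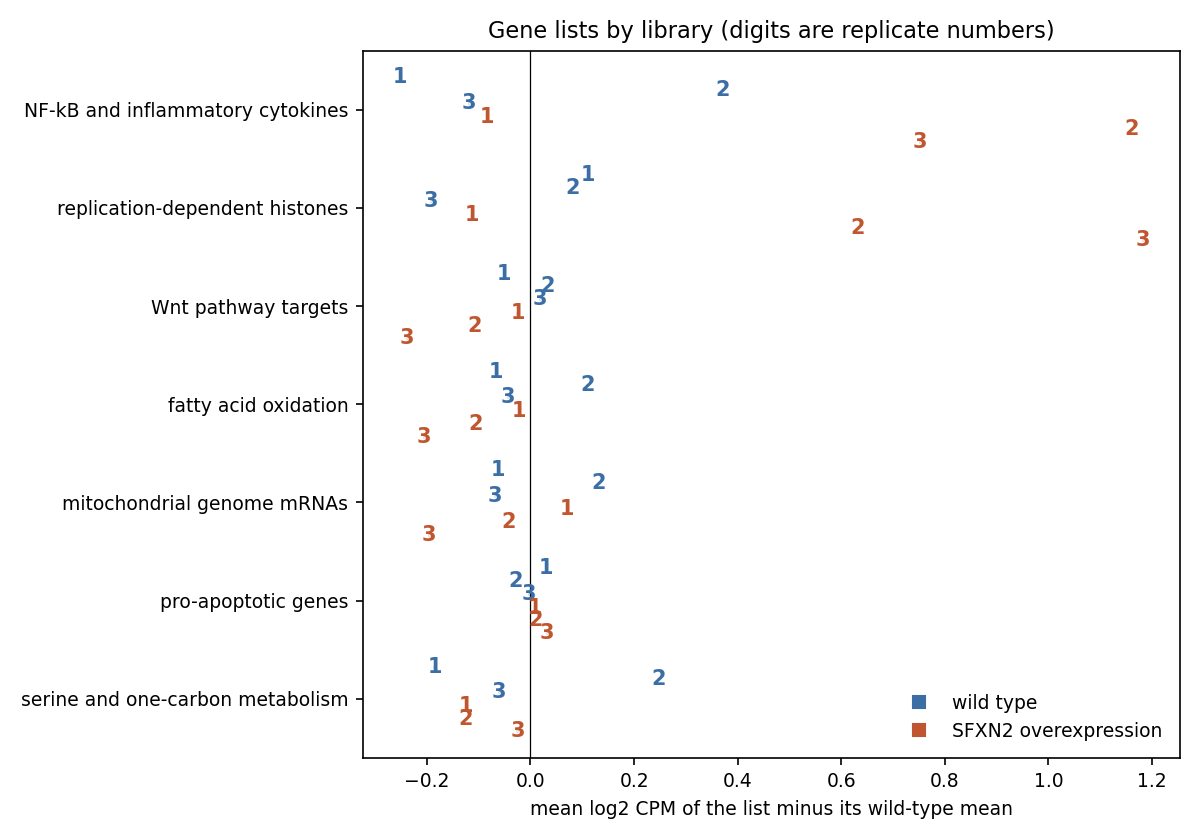
Mean log2 CPM of each gene list minus its wild-type mean (horizontal axis) for 7 lists, with a digit for each library giving its replicate number, blue for wild type and orange for SFXN2 overexpression. The NF-kB and histone lists are high in overexpression replicates 2 and 3 and lie near the wild-type libraries in replicate 1, and the pro-apoptotic list lies close to 0 in all 6 libraries.

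The other lists of signalling and growth did not pass. Interferon response genes (44 tested) had a median of 0.14, immediate-early genes (32 tested) 0.020, and TGF-beta targets and extracellular matrix genes (40 tested) -0.062, with camera adjusted p of 0.327, 0.33 and 0.853. Interferon response genes passed as higher without wild-type replicate 1 (0.0027) or overexpression replicate 1 (0.037), and immediate-early genes without wild-type replicate 2 (0.00019) or overexpression replicate 1 (0.012) and after GC correction with the replicate block (median 0.21, adjusted p = 0.030). Genes of S phase (35) and of G2/M phase (36) had medians of -0.028 and 0.018 (camera adjusted p = 0.562 and 0.835). Among markers of other cell types, the medians were 0.0049 for epithelial genes (10 tested), -0.038 for fibroblast and mesenchymal genes (11), 0.48 for neuronal genes (13), -0.11 for kidney tubule genes (7), 0.79 for blood and immune genes (5) and 0.17 for HeLa-type squamous genes (5). Their camera adjusted p values were 0.976, 0.976, 0.271, 0.271, 0.271 and 0.976. The neuronal and the blood and immune markers passed as higher without overexpression replicate 1 (0.0024 and 0.0011) and with DESeq2 (0.042 each). Over all 41 lists, 1007 genes other than SFXN2 were tested. Of these 0 passed in edgeR, 0 in DESeq2 and 0 in limma-voom, with 38, 50 and 33 at an unadjusted p below 0.05, and 0 passed in edgeR when adjusted over the list alone. With the replicate block in edgeR 0 passed as well, and 92 had an unadjusted p below 0.05.

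The most abundant transcripts were those of the mitochondrial genome and of translation. MT-CO1, a core subunit of cytochrome c oxidase, had a log2 fold change of -0.13, MT-CO2 of 0.022, MT-ND4, a complex I subunit, of -0.11 and EEF1A1, a translation elongation factor, of -0.092, none past the threshold in edgeR. MT-RNR2, the large mitochondrial ribosomal RNA, stood at 8212 ± 1493 and 9668 ± 266 CPM (SD, n = 3 each; edgeR adjusted p = 0.93).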

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

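The cyclic loess and both GC settings were chosen after seeing the data. SFXN2 kept its direction and call in all 18 refits, with log2 fold changes of 5.41 to 5.75 and a largest adjusted p of 0.00079. The count of 2 genes, 2 higher and 0 lower, was 9 (6 and 3) with DESeq2, 1 (1 and 0) with the replicate block, 1 (1 and 0) at an adjusted p of 0.01, and 4 (3 and 1) with the GC correction and replicate block. Leaving out 1 library gave 1 to 3 genes, 1 to 2 higher and 0 to 1 lower: 3 without wild-type replicate 1, and 1 without wild-type replicate 3 or overexpression replicate 2. C1QTNF3-AMACR lost its call with the block and in 5 of the 6 fits that left out a library. It kept the call with the GC correction and block (limma adjusted p = 0.019), in DESeq2 (adjusted p = 2.1e-07) and in limma-voom (adjusted p = 0.0029). The replicate block changed no other call. The 4 lists became 2 with the 1 CPM filter, 1 with cyclic loess (NF-kB), and 0 with an estimated correlation or fry. Leaving out 1 library gave 1 to 14 lists: 12 without wild-type replicate 2, 14 without overexpression replicate 1, 2 without wild-type replicate 3 or overexpression replicate 2, and 1 without overexpression replicate 3. The direction turned past the threshold, from higher to lower, for complexes II to V without overexpression replicate 1 (leave-one-out adjusted p range 0.0495 to 0.929), and without wild-type replicate 2 for the mitochondrial ribosome (0.00422 to 0.873), heat shock (0.00256 to 0.951) and ubiquitin-proteasome lists (0.00152 to 0.945). The cause was not tested. Of 2395 values of named genes, 2382 kept their side of the threshold, 6 lost and 7 gained a call and 0 turned past it; 74 changed sign with neither fit past the threshold. For lists, 766 of 818 values kept their side, 24 lost and 24 gained a call and 4 turned, and 90 changed sign with neither past. What depth alone limits was not separated from the spread between libraries.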

Other observations

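The tests of the whole locus of C1QTNF3-AMACR, of the removal of ribosomal RNA and of GC content were chosen only after the results were seen. Some genes outside the lists differed by a fold that a biologist may want to see again, although none passed in edgeR. SOX11, a transcription factor of neural development, stood at 6.66 ± 1.95 CPM (SD, n = 3) in wild type and 13.2 ± 2.25 CPM (SD, n = 3) with overexpression (edgeR adjusted p = 0.93). HSPB8, a small heat shock protein, stood at 2.04 ± 0.59 and 4.24 ± 0.42 CPM (SD, n = 3 each; edgeR adjusted p = 0.93). A gene without a symbol, ENSG00000288053, had no count in wild type and 15 to 47 counts with overexpression, at least 23.8-fold higher against a floor of 3 counts over the wild-type group (edgeR adjusted p = 0.516). It passed in DESeq2 (adjusted p = 0.0066) and limma-voom (adjusted p = 0.014). Other read-through gene models also lay higher, a test chosen after C1QTNF3-AMACR was seen and made without it. The median log2 fold change of 77 such models was 0.20, above all 10000 random lists matched on expression (middle 95% from -0.052 to 0.094), and 6 were higher at an unadjusted p below 0.05, which 2.15% of the random lists reached, although genes are not independent replicates. P2RX5-TAX1BP3 and URGCP-MRPS24 passed in DESeq2 (adjusted p = 0.018 and 0.024) and not in limma-voom (0.88 and 0.77), and the cause of this rise was not tested. Leaving out 1 library gave SOX11 log2 fold changes of 0.79 to 1.21, and GC correction gave 0.99.

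The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The real split gave 2 genes and the highest other split 9, and 4 of the 10 splits gave at least 2. For lists the real split gave 4 and the highest other 21, and all 10 splits gave at least 4. The split with 9 genes and 21 lists sets wild-type replicate 2 and overexpression replicates 2 and 3 against the rest, with 2703 genes at an unadjusted p below 0.05 against 895 for the real split. This points to a structure of the samples that does not follow the groups. Among the 4 splits that part all 3 numbered pairs, the real one gave 2 genes and 4 lists, and the others gave 0, 0 and 2 genes and 5, 9 and 10 lists.

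The NF-kB and histone lists were higher with overexpression, most in replicates 2 and 3, and the Wnt and fatty acid oxidation lists lower. All passed by camera with a preset correlation only. With an estimated correlation the camera adjusted p was 0.97, as for every pathway list, and fry gave 0 lists. The 1880 genes of lowest expression had a median log2 fold change of 0.17, and the 1880 of highest expression -0.016. A general rise of weakly expressed genes was set against 10000 random lists matched on expression. The medians lay at percentile 100 (NF-kB), 99.86 (histones), 0.32 (Wnt targets) and 2.55 (fatty acid oxidation). The fatty acid oxidation median of -0.0855 lies within the middle 95% of the random medians, -0.0861 to 0.0661. The NF-kB and histone percentiles argue against an even rise of all weakly expressed genes as the whole cause. They do not bear on a rise shared by genes that vary together, since the random genes were drawn independently. The estimated correlations were 0.35 (NF-kB) and 0.55 (histones). Both lists were picked by their calls in these data. Neuronal and blood and immune markers also lay higher in overexpression replicates 2 and 3, so such a rise stays open. Cyclic loess took the histone median from 0.57 to 0.54 and its camera adjusted p from 0.016 to 0.096. Over all alternatives that p ranged from 4.6e-05 to 0.97. The log2 fold changes correlated with GC content over genes (Spearman -0.25, and 0.018 after correction). By library, deviations from the gene means correlated with GC content at 0.32 in wild-type replicate 3 and between -0.17 and 0.10 elsewhere. After GC correction the adjusted p with the preset correlation was 0.00048 for NF-kB, 0.0061 for histones and 0.022 for fatty acid oxidation, all also past the threshold with the block, which argues against a GC trend as the whole cause. The correction left the NF-kB and histone medians near their values (0.54 and 0.57) and took the fatty acid oxidation median from -0.0855 to -0.135. For Wnt targets the camera adjusted p after GC correction was 0.0495, and 0.062 with the block. Their median went from -0.15 to -0.11, so a GC trend and an effect of SFXN2 cannot be told apart there. An effect of SFXN2 on these lists stays a hypothesis, and other differences between the libraries stay open, since each of the other splits gave more lists than the real one.

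C1QTNF3-AMACR was counted in all 3 overexpression libraries and in no wild-type library. Reads of the SFXN2 transcript placed there by shared sequence are argued against, since the longest stretch shared by their annotated transcripts is 21 bases, below the 30 set in advance. Its level added to that of AMACR would give a log2 rise of 0.15, under AMACR's upper 95% bound of 0.22, while added to C1QTNF3 it would give 1.01, over an upper bound of -0.0025. C1QTNF3 thus speaks against a rise through the whole locus and AMACR does not, and since reads may move between overlapping models, it stays open by a rule set after the values were seen. Vector sequence, a splice event near an insertion site and the rules of the read counter were not tested and stay open, as does a biological origin.

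Mitochondrial ribosomal RNA took a larger share of mitochondrial-genome counts with overexpression. It made up 12.6 ± 0.69% (SD, n = 3) of the ribosomal and messenger RNA counts of that genome in wild type and 15.7 ± 1.12% (SD, n = 3) with overexpression, higher in 3 of 3 libraries (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). MT-RNR1, the small ribosomal RNA, stood at 1011 ± 139 and 1362 ± 212 CPM (SD, n = 3 each; edgeR adjusted p = 0.93). Less complete removal of ribosomal RNA cannot be told apart from an effect of SFXN2, because nuclear ribosomal RNA had only 955 counts in all and its fold of 1.05 has a 95% interval of 0.72 to 1.54, which holds the 1.24-fold of the mitochondrial share. The nuclear fold is one of scaled counts and the mitochondrial fold one of a share within that genome, so the comparison is rough. A change in mitochondrial ribosomal RNA stays a hypothesis.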
